A study of Rattus norvegicus with 10 samples.

How the data were processed

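RNA was taken from muscle of Sprague Dawley rats with an RNeasy kit and made into libraries with a SMARTER mRNA-Seq kit, per the labels' protocols. The 10 samples carry the group labels NC (4), MPS (3) and TZG (3) and title numbers that no 2 samples share. Nothing in the labels states that the samples are separate animals, so each p-value measures only the spread between these samples. No batch, sequencing date, sex, dose or muscle is named.

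The deposit holds 2 tables with the same content, byte for byte, so 1 was used. It lists 32883 features with Ensembl rat gene identifiers, gene names and positions, of which 22250 are protein coding. The authors deposited a count per feature and sample, per the file headers, and the values are whole numbers that sum to between 12616160 and 18179144 per sample. The authors also deposited FPKM per sample, per the file headers; with a tolerance of 0.1%, FPKM equalled counts divided by gene length and library total in 100% of values with 50 or more counts. The table further gives log2 fold changes, p-values and q-values for the authors' 3 comparisons, per the file headers. The submitters' processing notes name fastp, HISAT2, StringTie 1.3.3b and edgeR 3.30.3 without saying what each did, with which options or on which genome build. How reads shared between gene copies or between strands were counted is not stated either. Only the counts entered the comparisons reported here; the deposited log2 fold changes and p-values are described in the closing part alone.

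Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes too low to test were removed with filterByExpr, libraries were scaled with TMM factors, and all 10 libraries entered 1 quasi-likelihood fit with 3 groups, so that the groups shared 1 estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM are counts-per-million of the library total, mitochondrial transcripts included, and normalised CPM are those of the TMM-scaled total. The standard error of a log2 fold change was taken from the fit's F statistic.

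Before the data were examined, 35 gene lists for muscle fibres, metabolism, inflammation, pain, matrix, stress and the other cells of a muscle piece were written down from general knowledge, with 798 entries, of which 755 matched a gene of the table. They were tested with camera in limma 3.58.1 on voom values at a preset correlation between genes of 0.01, with adjustment over the 35 lists, each of which had at least 5 measured members. Fold changes of list members come from edgeR. Names were matched to the table's own gene names, then through older names in a RefSeq table of the GRCr8 assembly, which served for names only. Where a name stood on more than 1 feature (291 names did), the feature with most counts was taken. After first values were seen, a few older names were found to have matched the wrong gene, among them mitochondrial genes matched to prostaglandin synthases, and the matching was corrected.

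The genes named in the text follow a rule that was set in advance as well. In each comparison it takes the 10 genes with the largest change in each direction among those that passed, had no overlap between the groups, averaged at least 1 CPM and carried a proper gene name; where none passed, it takes the 5 with the smallest p in each direction. It adds up to 4 members with the smallest p for each list spoken of, and 18 genes of inflammation, pain and muscle state whatever their result, of which 15 were in the table; Myh1, Myh2 and Chrng were not matched. Not every gene this rule takes is given in the text. The lymphoid, muscle, skin and fat genes given for single libraries were chosen after their values were seen.

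The alternatives set in advance were the DESeq2 1.42.0 test, RLE factors, no filter, a stricter filter at a mean of 5 CPM, limma-voom, a fit of the 2 compared groups only, an absolute log2 fold change of at least 1, an unadjusted p, camera with an estimated correlation, fry, and leaving out each sample. After the data were seen, the fit without MPS 14 was added as a result of its own with all these alternatives, and with it a correction of the counts for gene length and the slow fibre level as a covariate. Leaving out MPS 14 for TZG against NC and for the measures of opposite direction was added then too. Other splits of the samples were fitted in the same way, up to 35 for a comparison. Comparisons that share libraries were set beside 20 simulations with no effect. The random seed was 20240607, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

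The fits were tested on simulated counts with the real means and library sizes, in which 200 genes were changed. With all libraries, the share found at a 2-fold, 4-fold and 8-fold change was 0%, 24.6% and 53.5% for MPS against NC, 0%, 16.9% and 53.2% for TZG against MPS, and 1.61%, 33.8% and 62.5% for TZG against NC. Without MPS 14 it was 4.35%, 68.1% and 88.1%, 5.88%, 68.8% and 83.8%, and 18.2%, 66.2% and 85.5%. Unchanged genes were called as well: 4, 2 and 6 with all libraries, and 6, 13 and 7 without MPS 14. A simulated list of 40 genes changed 2-fold was found in all 6 cases, and unchanged lists were called in 1 case only (2 of 35, TZG against MPS with all libraries). Genes were drawn independently there, so the low number of false calls does not carry over to real lists, whose members can move together. Other splits of the real samples called up to 23 of 35 lists. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.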

Results

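Messenger RNA was sequenced from muscle of Sprague Dawley rats in 10 libraries: 4 labelled NC, 3 labelled MPS and 3 labelled TZG. MPS stands for myofascial pain syndrome, a condition of painful, taut spots in skeletal muscle. The sample titles call TZG a drug, and the series concerns Tianhe Zhuifeng liquid extract, a herbal preparation. The labels spell out neither NC nor TZG, name no muscle, dose or time, and do not state whether the TZG animals had the pain model. The total counts were 15738812, 13324242 and 14090093 in TZG 26, 27 and 43, and 16497745, 18179144 and 13642002 in MPS 10, 11 and 14. In NC 4, 5, 6 and 7 they were 13581646, 12616160, 13426347 and 13453447. Transcripts of the mitochondrial genome took between 18.3% (TZG 26) and 38.1% (TZG 43) of counts in 9 of the libraries and 9.47% in MPS 14.

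The library MPS 14 held high levels of lymphoid genes and low levels of muscle genes. Glycam1, a mucin-like protein of the high endothelial vessels of lymph nodes (ENSRNOG00000036826, chromosome 7, 145172493 to 145174771), had 21278 counts in MPS 14 and 0 in the other 9 libraries. That is at least 68100-fold higher against a floor of 3 counts over those 9. The genome build of the positions given here and elsewhere is not given in the sources used. Ccl21 and Cxcl13, the chemokines that draw lymphocytes into T cell zones and B cell follicles, stood at 1325 and 791.9 counts-per-million (CPM) there and at no more than 4.68 and 6.03 CPM elsewhere. Cr2, the complement receptor of B cells and follicular dendritic cells, stood at 846.9 CPM against at most 0.372, and Ptprc, the phosphatase CD45 carried by all leukocytes, at 1887 against at most 11.1. The T cell gene Cd3e was at 287.1 CPM and the B cell gene Ms4a1 at 262.6 CPM. Muscle genes went the other way. Acta1, the actin of skeletal muscle, was at 2320 CPM or 5.53% of the median of the other 9. Ckm (muscle creatine kinase), Myh4 (the fastest myosin heavy chain) and Tnnt3 (fast troponin T) were at 4.16%, 3.86% and 3.87%. Across genes, MPS 14 correlated with the others at a median r of 0.684, while the other 9 correlated among themselves at 0.886 to 0.967; genes are not independent replicates. Each comparison is therefore given with all libraries, as planned, and again without MPS 14, a choice made after these values were seen.

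**Figure D1:**
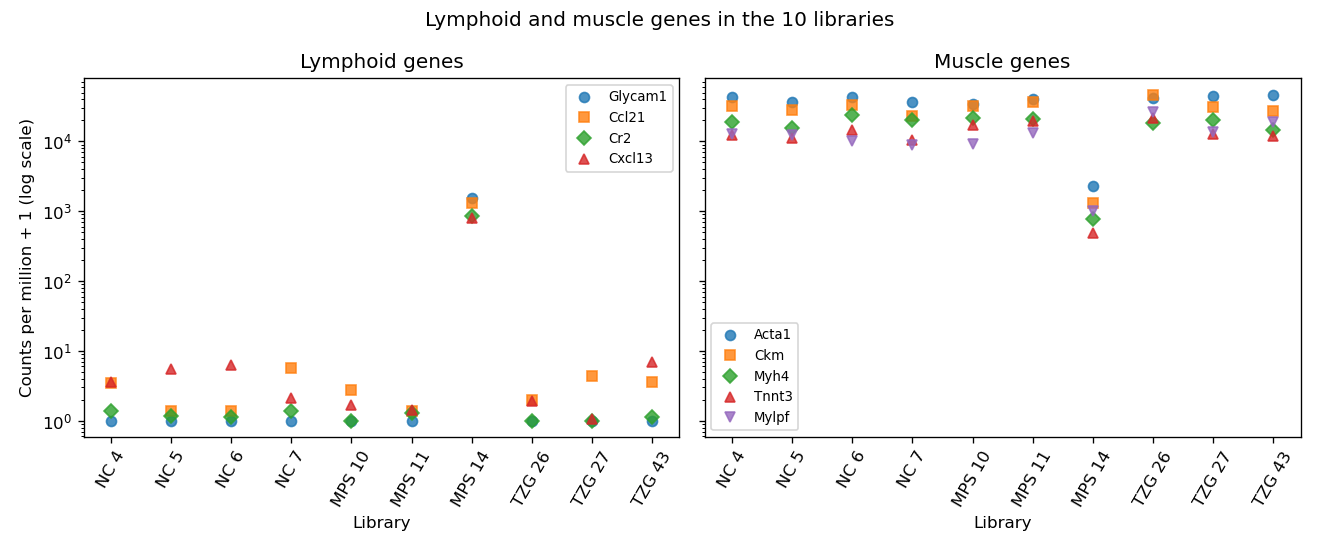
CPM plus 1 on a log axis for 4 lymphoid genes (Glycam1, Ccl21, Cr2, Cxcl13) and 5 muscle genes (Acta1, Ckm, Myh4, Tnnt3, Mylpf), with 1 symbol and colour per gene and 1 point per library. MPS 14 lies alone at the top of the lymphoid genes (Glycam1 1560 CPM against 0) and alone at the bottom of the muscle genes (Acta1 2320 CPM against a median of 41950).

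The comparison of MPS with NC asks how muscle labelled MPS differs from muscle labelled NC. With all libraries, genes of the cytosolic ribosome rose as a list, with 87 of 89 members higher in MPS at a median log2 fold change of 0.79 (camera adjusted p = 4.75e-20; adjusted p = 0.0904 with an estimated correlation). Genes of slow-twitch fibres rose too, with 11 of 11 higher at a median of 5.55 (camera adjusted p = 2.86e-05), and so did genes of cell proliferation, with 20 of 21 higher at a median of 1.79 (0.000166); both had an adjusted p = 0.713 with an estimated correlation. Markers of fibroblasts and fibro-adipogenic progenitors, the matrix-producing cells between fibres, fell as a list, although 5 of 14 were higher (median -0.84; camera adjusted p = 0.000167, and adjusted p = 0.0904 with an estimated correlation). Endothelial markers fell with 14 of 15 lower (median -0.45; camera adjusted p = 0.0297, and adjusted p = 0.713 with an estimated correlation). The list of pain mediators and receptors fell with a median of -0.34 (camera adjusted p = 0.0464, and adjusted p = 0.396 with an estimated correlation).

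Among slow fibre genes, Tnnt1 (slow troponin T) had a log2 fold change of 8.74. Tpm3 (slow tropomyosin) had 2.62 ± 0.74 (SE), with 268 ± 136 normalised CPM (SD, n = 3) against 43.6 ± 6.32 (n = 4), both at an edgeR adjusted p of 0.398. Ribosomal members included Rpl35a at 1.34 and Rps21 at 1.62, both at an edgeR adjusted p of 0.305. In the fibroblast list, Dcn (decorin, a collagen-binding proteoglycan) stood at -1.51 and Mfap5, a microfibril protein, at -1.65. In the pain list, the endothelin receptors Ednra and Ednrb stood at -1.40 and -1.87. Lymphocyte genes reached a median of 4.12, with Cd3g at 51.8 ± 89.6 normalised CPM in MPS (SD, n = 3), and their list did not pass (camera adjusted p = 0.0767). The proliferation genes Mcm3, a replication helicase subunit, at 3.14 and Kif11, a spindle motor, at 4.08 moved with these lymphoid genes of MPS 14. The inflammatory cytokine list had a median of 0.46 and a mean of 0.49 while its camera test pointed down (adjusted p = 0.249).

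In all, limma's camera called 13 of 35 lists at its preset correlation, 3 up and 10 down, and none with an estimated correlation. The other 7 that fell were circadian clock (camera adjusted p = 0.00296), glycolysis (0.00424), atrophy (0.0116), muscle regeneration (0.0204), matrix (0.0413), fatty acid oxidation (0.0464) and antioxidant genes (0.0468), with medians between -0.37 and -0.11. Antioxidant genes had a camera adjusted p = 0.523 with an estimated correlation and the other 6 had 0.713. Many of these calls rest on MPS 14. Without it, camera kept 3 of the 13 in the same direction (ribosome, slow fibre and fibroblast genes). The median of cell proliferation, MPS vs NC, became -0.066 (camera adjusted p = 0.84), that of endothelial genes -0.028 (0.848), that of the pain list -0.18 (0.274) and that of muscle regeneration 0.033 (0.972). The medians of glycolysis and fatty acid oxidation turned to 0.27 and 0.13. No gene passed among 13535 tested by edgeR (smallest adjusted p = 0.211), DESeq2 called 205 genes and limma-voom 0. An unadjusted p under 0.05 held for 1453 genes, where 676.8 are expected by chance. Adjusted over the list alone, 11 ribosomal, 8 slow fibre, 8 lymphocyte, 5 fibroblast and 1 pain gene passed, against 0 over all genes.

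The smallest adjusted p belonged to 2 features that carry only a locus or clone name. The properly named genes of at least 1 CPM with the smallest p, none of which passed, were higher for Ramp1, a subunit of the receptor for the pain peptide CGRP (log2 fold change 2.49 ± 0.42 SE), the haem exporter Flvcr1 (1.79), the transporter Slc16a6 (2.42), Rpl12 (1.59) and Rpl13 (1.97). They were lower for the heparan sulphate enzyme Hs3st1 (-1.97), the growth factor inhibitor Spry2 (-1.17), the urokinase gene Plau (-1.62), the vesicle fusion sensor Doc2b (-2.80) and Ltc4s, the synthase of leukotriene C4 (-4.52). All 10 had an edgeR adjusted p of 0.305. Il1b, a fever-causing cytokine, stood at 2.17 (edgeR adjusted p = 0.453), with 28.6 CPM in MPS 14 and 0.976 to 3.55 CPM in the other 9 libraries. Ccl2 stood at 0.85 and Ptgs2, the inducible prostaglandin synthase, at 0.19. Myog stood at -1.29, Col1a1 at -0.60, Ppargc1a at -0.45, Myh7 at 9.46, Myh4 at -0.16, and the ubiquitin ligases of muscle wasting Fbxo32 and Trim63 at -1.41 and 0.24. None of these passed, and Il6, Tnf, Tac1 and Calca were too low to test. Tac1, the substance P gene, had 0 counts in all 10 libraries and Calca, the CGRP gene, 5 counts, all in NC 5.

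Without MPS 14, 362 genes changed between MPS 10 and 11 and the 4 NC libraries, 307 up and 55 down (edgeR, adjusted p under 0.05, 13719 genes). Camera called 15 lists, 9 up and 6 down: genes of nerve sheath, of slow fibres, of nuclear-encoded oxidative phosphorylation and of the ribosome were among those that rose, and markers of macrophages, fibroblasts and the interferon response among those that fell. Ribosomal proteins passed camera with an estimated correlation (adjusted p = 0.00648), and the other 14 lists did not (adjusted p = 0.102 to 0.622). Scamp1, a membrane protein of secretory vesicles (ENSRNOG00000061582, chromosome 2, 23857995 to 23941084), had the smallest p of all: it fell by 3.09 ± 0.29 on the log2 scale (SE; edgeR adjusted p = 0.00193), from 29.5 ± 6.67 normalised CPM (SD, n = 4) to 3.46 ± 0.562 (n = 2). Csrp3, the muscle LIM protein of the sarcomere's Z-disc (ENSRNOG00000014327, chromosome 1, 104147206 to 104166367), rose by 5.56 ± 1.02 (edgeR adjusted p = 0.0346), from 2.55 ± 0.954 (SD, n = 4) to 121 ± 106 normalised CPM (n = 2).

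The Schwann cell and nerve list rose, with 10 of 12 members higher at a median of 1.77 (camera adjusted p = 5.9e-05; adjusted p = 0.269 with an estimated correlation). Prx, periaxin of the myelin sheath, rose by 2.43 ± 0.30 (SE; edgeR adjusted p = 0.00984) to 35.4 ± 8.43 normalised CPM (SD, n = 2) from 6.57 ± 2.19 (n = 4), and Mag, a myelin adhesion protein, rose by 5.54 (edgeR adjusted p = 0.0356). Mag had 67 and 21 counts in MPS 10 and 11, against 2, 0, 0 and 1 in NC 4, 5, 6 and 7. The size of its rise rests on these few counts. Pmp2, a lipid-binding protein of peripheral myelin, rose by 7.03 ± 1.25 (edgeR adjusted p = 0.0181) to 5.38 normalised CPM. Mbp (3.86) and Pmp22 (1.40), both myelin genes, did not pass. The slow fibre list rose with 11 of 11 members higher at a median of 6.13 (camera adjusted p = 3.04e-06; adjusted p = 0.269 with an estimated correlation). Myh7b, a slow myosin heavy chain, rose by 2.67 ± 0.56 (edgeR adjusted p = 0.0354). Myh7, the slow myosin heavy chain itself (ENSRNOG00000016983, chromosome 15, 33634422 to 33656089), stood at 897 ± 408 normalised CPM (SD, n = 2) against 0.851 ± 1.23 (n = 4) and did not pass (log2 fold change 10.03 ± 2.63, edgeR adjusted p = 0.104).

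Sln, sarcolipin, which slows the calcium pump of the sarcoplasmic reticulum, rose by 3.34 ± 0.47 (SE; edgeR adjusted p = 0.0113) to 19 normalised CPM from 1.86. The calcium handling list rose with 15 of 20 higher (median 0.54; camera adjusted p = 0.000861, and adjusted p = 0.216 with an estimated correlation), and in it Pvalb, the calcium buffer of fast fibres, rose by 1.48, Camk2b, a calcium-dependent kinase, by 1.73, and Hrc, a calcium-binding protein of the reticulum, by 1.10. Fast fibre genes rose as a list too, with 13 of 13 higher at a median of 0.47 (camera adjusted p = 0.00053; adjusted p = 0.393 with an estimated correlation). TMM factors in this fit were 0.991 and 0.914 in MPS 10 and 11, 0.734 to 0.974 in TZG and 1.064 to 1.295 in NC. This scaling raised MPS and TZG against NC in every gene, and the counts of members higher or lower depend on it. In plain CPM, Myh4 stood at 21420 and 21250 in MPS 10 and 11, inside the NC range of 15400 to 23800. Tnnt3 stood at 17350 and 19380, above the NC range of 10630 to 14540.

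Oxidative phosphorylation genes rose with 48 of 49 higher at a median of 0.75 (camera adjusted p = 5.98e-17; adjusted p = 0.393 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, rose by 1.62 ± 0.29 (SE; edgeR adjusted p = 0.0223) to 764 ± 78.4 normalised CPM (SD, n = 2) from 248 ± 56.4 (n = 4), and the complex I subunits Ndufv1 and Ndufa5 rose by 1.16 and 1.14. The genes of the mitochondrial genome did not move with them (median -0.047, 6 of 13 higher; camera adjusted p = 0.848). The citric acid cycle list rose with a median of 0.43 (camera adjusted p = 0.00109; adjusted p = 0.537 with an estimated correlation) and the glycolysis list with a median of 0.27 (0.0317, and adjusted p = 0.622 with an estimated correlation). In them, Dlst, a subunit of the oxoglutarate dehydrogenase complex, rose by 0.99, Gapdh by 1.19 and the lactate transporter Slc16a3 by 1.56. Ribosomal protein genes rose with 72 of 89 higher at a median of 0.43 (camera adjusted p = 3.32e-08). Among them, Rpl13 rose by 2.31 ± 0.24 (SE; edgeR adjusted p = 0.00406), Rps28 by 1.92, Rps19l2 by 1.90 and Rpl35a by 1.54. Fold changes across genes fell with gene length (Spearman rho = -0.195, genes not being independent), and ribosomal and respiratory genes are short.

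Interferon response genes fell as a list with 25 of 26 lower at a median of -1.24 (camera adjusted p = 8.09e-07, and adjusted p = 0.469 with an estimated correlation). Irgm, Ifi44 and Ifi44l, all interferon-induced, were lower by 1.45, 1.44 and 2.30. Over all genes, 2 members of the list passed in edgeR and 24 did not, so not all of these genes passed. The interferon list varied within NC, from 3.13 mean log2 CPM in NC 5, below MPS 10 (3.38), to 4.99 in NC 6. Macrophage markers fell with 22 of 22 lower at a median of -1.54 (camera adjusted p = 3.7e-06; adjusted p = 0.197 with an estimated correlation), although no member passed over all genes. Lyz2, lysozyme, stood at -1.67 (edgeR adjusted p = 0.0776), with 36 ± 3.15 normalised CPM (SD, n = 2) against 114 ± 38.4 (n = 4), and the Fc receptor Fcgr1a stood at -2.43. The fibroblast list fell with 12 of 14 lower at a median of -1.26 (camera adjusted p = 2.64e-05; adjusted p = 0.102 with an estimated correlation). Pdgfra, the receptor that marks fibro-adipogenic progenitors, fell by 1.32 ± 0.27 (SE; edgeR adjusted p = 0.0317), and Dcn fell by 1.57 to 192 ± 1.86 normalised CPM (SD, n = 2) from 570 ± 134 (n = 4). The cytokine list fell with 17 of 18 lower (median -0.80; camera adjusted p = 0.000659, and adjusted p = 0.102 with an estimated correlation), with Il18 at -3.38 and Cxcl9 at -1.27, neither past the threshold. Antigen presentation (median -0.78; camera adjusted p = 0.00156) and NF-kB genes (-0.38; 0.00271) fell as lists, with an adjusted p = 0.487 and an adjusted p = 0.102 with an estimated correlation. Adipocyte markers rose as a list (median 0.88; camera adjusted p = 0.0325, and adjusted p = 0.393 with an estimated correlation), although Pnpla2, the lipase that starts fat breakdown, fell by 3.39.

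Of the other genes with the largest changes, those that rose were Cox7a1, the muscle form of a cytochrome c oxidase subunit, by 5.29 ± 1.03 (SE; to 4.83 normalised CPM), and the transcription elongation factor-like genes Tceal5 and Tceal6 by 4.57 ± 0.69 and 4.05 ± 0.84. So did the secreted protein gene Wfdc1 by 3.09, Barx2, a homeobox factor of muscle progenitors, by 3.02, Pmepa1, a brake on TGF-beta signalling, by 2.98, and Ramp1 by 2.72 ± 0.40. Those that fell were Ltc4s by 3.97, MGC105567 by 3.15, the nucleotide receptor P2ry6 by 3.04, osteoprotegerin (Tnfrsf11b) by 2.92, the phospholipase Pla2g2d by 2.84, Doc2b by 2.79 and the matrix protein Efemp1 by 2.45. In edgeR their adjusted p lay between 0.0113 and 0.0499. In each, both MPS libraries lay outside the range of the 4 NC libraries, which the rule for naming genes requires. Groups did not overlap in 38.6% of all genes tested. Il1b (-0.19), Ccl2 (-0.86), Ptgs2 (-1.78), Myh4 (0.42), Fbxo32 (-1.04), Trim63 (0.80), Myog (-0.76), Col1a1 (-0.53) and Ppargc1a (0.13) did not pass. Ribosomal and Tceal genes have near-identical copies, and how reads were shared between them is not stated.

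Adjusted over the list alone, 34 oxidative phosphorylation genes, 24 ribosomal genes that were higher and 1 that was lower, and 9 slow fibre, 9 calcium, 7 interferon, 6 macrophage, 6 fibroblast and 3 Schwann cell genes passed. Over all genes, 8 oxidative phosphorylation, 9 ribosomal, 1 slow fibre, 3 calcium, 2 interferon, 0 macrophage, 2 fibroblast and 2 Schwann cell genes passed in edgeR. The count of 362 rests on few libraries: leaving out MPS 10 or MPS 11 left 2 and 7, and leaving out NC 4, 5, 6 or 7 left 104, 42, 49 and 32. With the slow fibre level as a covariate edgeR called 0, while limma-voom without it called 387 and DESeq2 1100, and 2826 had an unadjusted p under 0.05.

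**Figure D2:**
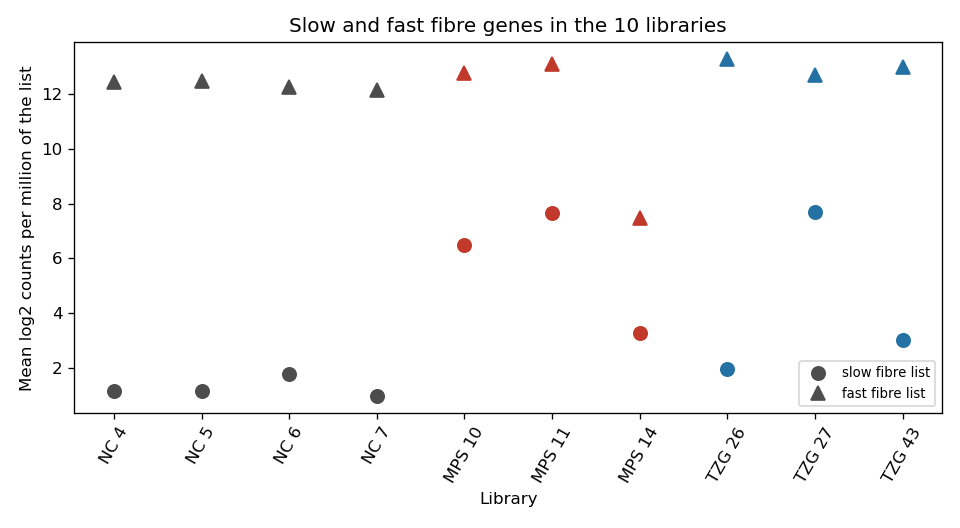
Mean log2 CPM of the slow fibre list and of the fast fibre list, with 1 point per library, coloured by group. The slow fibre list stands at 6.47 and 7.66 in MPS 10 and 11 and at 7.69 in TZG 27, at 3.26 in MPS 14, and between 0.97 and 1.78 in NC, while the fast fibre list lies between 12.1 and 13.3 in all libraries but MPS 14 (7.49).

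The slow fibre level varied between single libraries as well as between groups. The mean log2 level of slow minus fast fibre genes was -5.32 ± 1.04 in MPS (SD, n = 3), -8.76 ± 3.32 in TZG (n = 3) and -11.05 ± 0.385 in NC (n = 4). MPS exceeded NC by 5.73 in a two-sided exact permutation test (p = 0.0286, the smallest that 35 splits can give, Benjamini-Hochberg adjusted 0.0857 over 3 comparisons, which does not pass). MPS 14, with its few muscle genes, had the highest value (-4.22). Without it, a test added after the data were seen, MPS exceeded NC by 5.18 (exact permutation p = 0.0667, the smallest that 15 splits can give, adjusted 0.2). The differences of TZG from MPS (-3.44, exact permutation p = 0.3, adjusted 0.3) and from NC (2.29, exact permutation p = 0.143, adjusted 0.214) did not pass, and 3 libraries against 3 cannot give an exact p below 0.1. Within TZG, Myh7 stood at 1310 CPM in TZG 27, 26.8 in TZG 43 and 0.191 in TZG 26, and Tnnt1 at 468.9, 4.47 and 0.635 CPM.

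The comparison of TZG with MPS asks how muscle labelled TZG differs from muscle labelled MPS. It measures an effect of the extract on the pain model only if the TZG animals had the model, which the labels leave open. With all libraries, lists of muscle and energy metabolism rose and lists of immune and dividing cells fell at camera's preset correlation, and these are the genes in which MPS 14 stands apart. No list passed with an estimated correlation (camera adjusted p = 0.634 with an estimated correlation for interferon and adjusted p = 0.598 for each of the other 19 called). Oxidative phosphorylation rose with 45 of 49 members higher in TZG (median 0.43), the citric acid cycle with 21 of 21 (0.42), glycolysis with 24 of 26 (0.66), fast fibre genes by a median of 0.65 and the mitochondrial genome with 13 of 13 higher (0.93). Proliferation genes fell with 21 of 21 lower (median -1.52), antigen presentation with 20 of 20 (-1.45), and the interferon response (-0.84) and NF-kB signalling (-0.75) fell as well.

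Examples were Cox5a at a log2 fold change of 0.79, Ndufs1 at 0.54 and Ldha, lactate dehydrogenase, at 0.97. On the lower side the class II antigen gene RT1-Da stood at -3.41 ± 1.37 (SE), with 36.8 ± 14.4 normalised CPM in TZG (SD, n = 3) against 390 ± 637 in MPS (n = 3). Mx1, an antiviral GTPase, stood at -4.05, Birc3, an inhibitor of cell death, at -2.39, Nfkb1 at -1.33 and Mcm3 at -3.35. None of these genes passed. Camera called 20 lists. Its adjusted p was 3.33e-07 for oxidative phosphorylation, 1.44e-05 for glycolysis, 3.18e-05 for the citric acid cycle, and 0.00038 for fast fibre and for the mitochondrial genome. For the lists that fell it was 0.00123 for proliferation, 0.00164 for antigen presentation, 0.00254 for NF-kB and 0.00664 for interferon. The others that rose by camera were erythroid (adjusted p = 0.000806, median 1.32), denervation (0.0035), fatty acid oxidation (0.00392), calcium handling (0.0047), matrix (0.00553), regeneration (0.00582), fibroblast (0.0103), adipocyte (0.0127, median 1.31), antioxidant (0.0309) and circadian genes (0.048). Slow fibre genes fell by camera (adjusted p = 0.0161, median -0.43), but not in TZG 27. Their list stood at 7.69 mean log2 CPM there, 7.66 in MPS 11, and 1.97 and 3.01 in TZG 26 and 43. Without MPS 14, 10 of these lists turned direction, among them oxidative phosphorylation, interferon and proliferation (medians -0.0094, 0.074 and 0.55), and adipocyte, TZG vs MPS, turned without TZG 43 (-0.098). Other calls ended without MPS 14: citric acid cycle (median 0.042, camera adjusted p = 0.366), glycolysis (0.10, 0.37) and fast fibre genes (0.11, 0.587). The erythroid (0.81, camera adjusted p = 0.157) and adipocyte calls (1.33, 0.589) ended there as well.

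No gene passed among 13535 in edgeR (smallest adjusted p = 0.78), 700 had an unadjusted p under 0.05 (676.8 expected by chance), DESeq2 called 3 and limma-voom 0. Among properly named genes of at least 1 CPM, the smallest p on the higher side belonged to the reductase Akr1b7 (4.89 ± 1.06 SE), the cytochrome P450 gene Cyp4f18 (2.79), Cish, an inhibitor of cytokine signalling (1.94), the fat cell gene Medag (2.30) and the collagen receptor Itga11 (1.77). On the lower side they were Mier3, a transcriptional repressor (-2.10 ± 0.44 SE), Ctxn3 (-2.84), the ganglioside enzyme B4galnt1 (-2.58), the replication factor Lrwd1 (-1.02) and Kank4 (-2.34). Il1b stood at -1.31, Ccl2 at -1.23, Ptgs2 at -0.55, Col1a1 at 2.6, Myh7 at -0.40, Myh4 at 0.45, Trim63 at -0.17, Fbxo32 at 0.13, Myog at 0.36 and Ppargc1a at 0.92, none past the threshold.

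Without MPS 14, Scamp1 was the only gene that edgeR called between TZG and MPS. It rose by 2.94 ± 0.30 (SE; edgeR adjusted p = 0.00774), to 26.5 ± 4.71 normalised CPM (SD, n = 3) from 3.46 ± 0.562 (n = 2), with NC at 29.5 ± 6.67 (n = 4). MPS 14, left out of this fit, had 60.04 CPM of Scamp1 before TMM scaling, where NC 7 had 44.3 and MPS 10 and 11 had 3.03 and 3.52. Markers of Schwann cells fell as a list with 10 of 12 lower in TZG (median -1.78, camera adjusted p = 8.55e-09). So did slow fibre genes with 11 of 11 lower (-0.96, camera adjusted p = 1.38e-08), both at an adjusted p = 0.44 with an estimated correlation. Neither fall held in every TZG library. The Schwann cell list stood at 3.70 mean log2 CPM in TZG 43, above MPS 11 (3.61), and at 1.54 and 1.94 in TZG 26 and 27. The slow fibre list stood at 7.69 in TZG 27, above MPS 10 and 11 (6.47 and 7.66), and at 1.97 and 3.01 in TZG 26 and 43. Macrophage markers rose with 21 of 22 higher (median 1.29; camera adjusted p = 1.18e-06), lymphocyte markers with 10 of 11 (1.75; 6.89e-05) and fibroblast markers with 13 of 14 (0.98; 6.89e-05), at an adjusted p = 0.47, 0.44 and 0.44 with an estimated correlation. Inside these lists no member passed over all genes. The rises lean on TZG 43, although camera still called these 3 lists without it (adjusted p under 0.05). The medians were then 0.44 for macrophage, 0.95 for lymphocyte and 0.35 for fibroblast markers, and the macrophage list of TZG 27, at 2.15 mean log2 CPM, lay below MPS 10 (2.46) and MPS 11 (2.31).

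Prx stood at -2.19 ± 0.33 (SE; edgeR adjusted p = 0.184), with 7.75 ± 1.66 normalised CPM (SD, n = 3) against 35.4 ± 8.43 (n = 2), and Pmp22 at -1.40. Lyz2 stood at 1.34, with 91 ± 47.3 normalised CPM (SD, n = 3) against 36 ± 3.15 (n = 2), the scavenger receptor Msr1 at 3.09 and Fcgr1a at 2.24. Pdgfra stood at 0.82 and Gsn, the actin-severing protein gelsolin, at 1.11. Of the lymphocyte genes, Il2rb, an interleukin 2 receptor chain, stood at 2.67 and Nkg7, a granule protein of killer cells, at 2.16. The cytokine list rose with 15 of 18 higher (median 0.74; camera adjusted p = 0.00092, and adjusted p = 0.368 with an estimated correlation), with Il18 at 3.01 and Ccl5 at 1.81. The matrix list rose with 27 of 33 higher (0.86; camera adjusted p = 0.00126, and adjusted p = 0.485 with an estimated correlation), a call that ended without TZG 43 (0.30; 0.161). Glucocorticoid response genes fell as a list (median -0.43; camera adjusted p = 3.95e-06, and adjusted p = 0.44 with an estimated correlation), with Arrdc2 at -3.14, Per1 at -1.03 and Klf9 at -0.62. Immediate early genes (-0.49; camera adjusted p = 0.00386) and pericyte markers (-0.37; 0.00108) fell too, both at an adjusted p = 0.47 with an estimated correlation. Endothelial markers were called as lower by camera (adjusted p = 0.00108, and adjusted p = 0.613 with an estimated correlation), with a median of -0.35 and a mean of 0.35, the tight junction gene Cldn5 being listed at 0 in MPS 10 and MPS 11. Col1a1 stood at 2.55, with 968 ± 1406 normalised CPM in TZG (SD, n = 3), Il1b at 1.05, Ccl2 at 0.50 and Ptgs2 at 1.45. Myh7 stood at -0.96, Myh4 at -0.12, Fbxo32 at -0.23, Trim63 at -0.74, Myog at -0.16 and Ppargc1a at 0.35, and none of these passed.

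Of 15 lists called, camera also had antioxidant genes (adjusted p = 0.00422, median 0.22), mitochondrial genome (0.00921, median 0.45), NF-kB (0.00995, median 0.23) and antigen presentation genes (0.0174, median 0.33) as higher. Their adjusted p was 0.47, 0.685, 0.44 and 0.633 with an estimated correlation in camera. Without TZG 43 the endothelial median turned to 0.062 and that of mitochondrial genome, TZG vs MPS, without MPS replicate 14, to -0.049. Adjusted over the list alone, 2 Schwann cell, 2 lymphocyte and 1 fibroblast gene passed, against 0 over all genes. The count of 1 gene became 2 without TZG 26, 0 in limma-voom and 14 in DESeq2. An unadjusted p under 0.05 held for 575 genes, fewer than the 686 expected by chance.

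**Figure D3:**
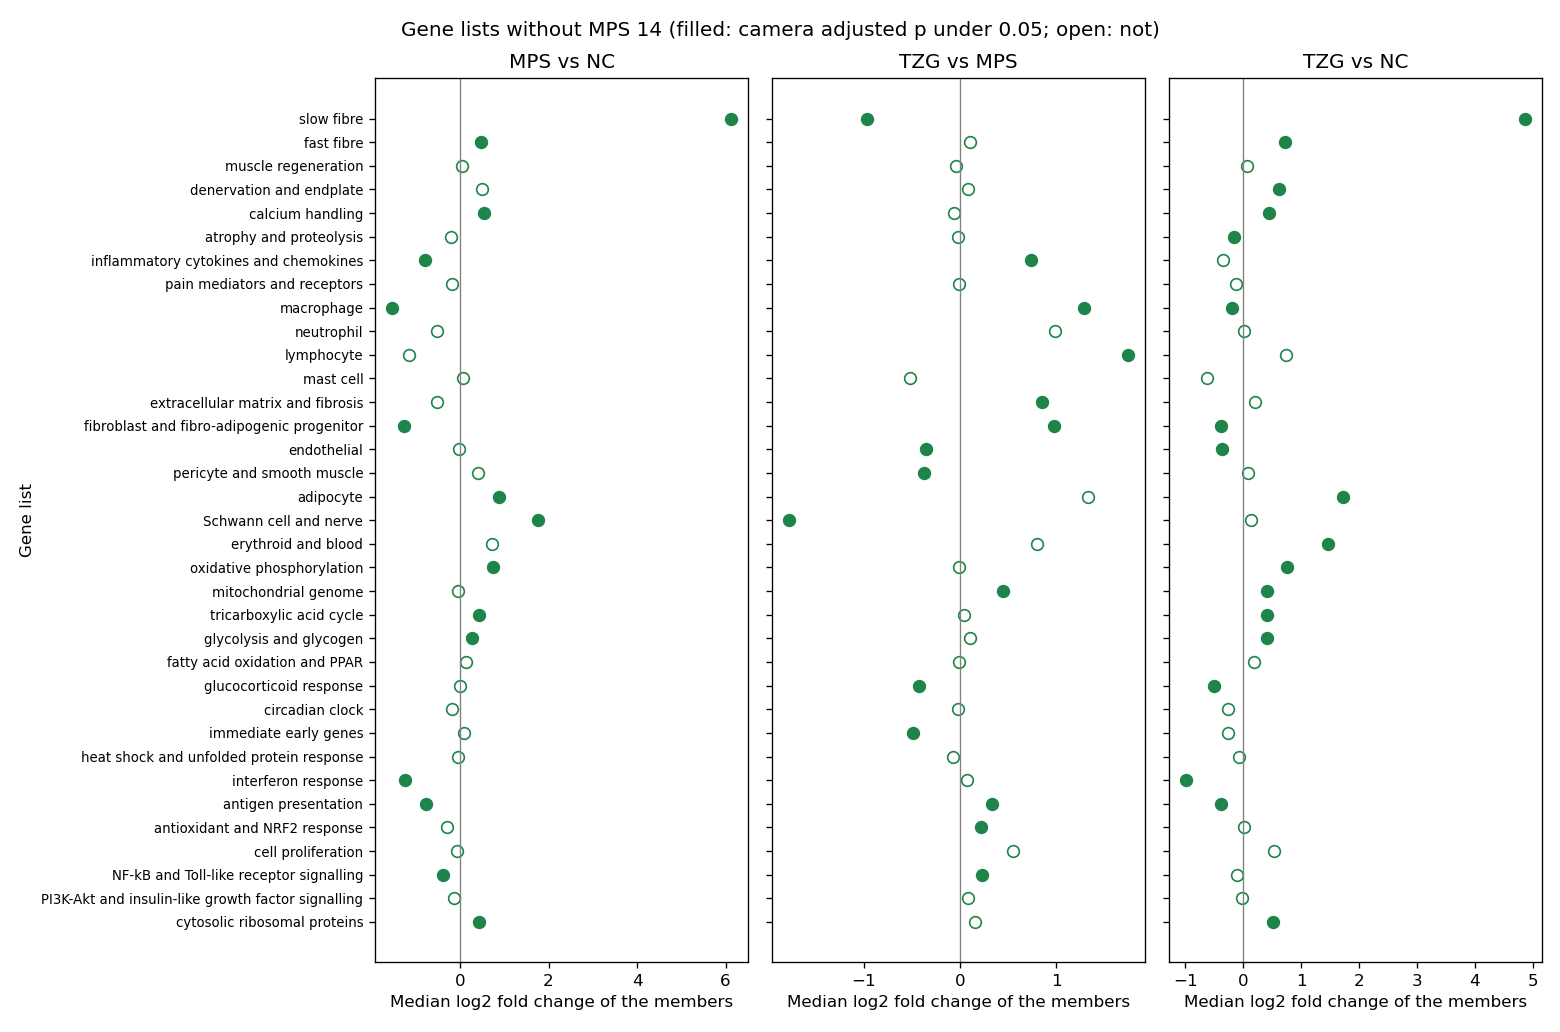
Median log2 fold change of each of the 35 gene lists in the 3 comparisons without MPS 14, with 1 point per list and comparison; filled points passed camera at the preset correlation. Slow fibre genes lie farthest to the right against NC (6.13 in MPS and 4.87 in TZG), and the macrophage list is at -1.54 in MPS against NC and at 1.29 in TZG against MPS.

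The comparison of TZG with NC asks how muscle labelled TZG differs from muscle labelled NC. With all libraries, ribosomal protein genes rose with 84 of 89 members higher (median 0.51; camera adjusted p = 5.82e-22), oxidative phosphorylation with 48 of 49 (0.74; 3.35e-09), slow fibre genes by a median of 4.86 (0.000481), adipocyte markers by 1.69 (0.000608), the citric acid cycle by 0.40 (0.00221) and erythroid genes by 1.45 (0.0283). Interferon response genes fell with 26 of 26 lower (median -1.0; camera adjusted p = 7.84e-07), and endothelial (-0.38; 0.00587), glucocorticoid response (-0.51; 0.00597) and fibroblast genes (-0.38; 0.0405) fell as lists. Each of these 10 had an adjusted p = 0.883 with an estimated correlation in camera. The interferon list of NC 5 (3.13 mean log2 CPM) lay inside the TZG range of 3.05 to 3.23. The slow fibre rise rests on TZG 27: the mean log2 CPM of that list was 7.69 there, 3.01 in TZG 43 and 1.97 in TZG 26, against 0.97 to 1.78 in NC, and without TZG 27 the median of slow fibre, TZG vs NC, was 0.61 (camera adjusted p = 0.157). Without TZG 43, erythroid and blood, TZG vs NC, had 0.66 (0.18) and adipocyte, TZG vs NC, had 0.38 (0.0219). Adjusted over the list alone, 8 ribosomal, 6 slow fibre and 4 adipocyte genes passed, against 0 over all genes.

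Ndufb8, a complex I subunit, stood at 1.41, Rps16 at 1.49, the fat synthesis genes Scd and Fasn at 8.06 and 3.82 (644.6 and 280.3 CPM in TZG 43, against at most 12.3 and 19.3 in TZG 26 and 27), and the interferon-induced genes Ifit1, Ifit2 and Ifit3 at -2.32, -1.21 and -1.57, with Ifit1 at 7.34 ± 2.62 normalised CPM in TZG (SD, n = 3) against 36.6 ± 20.1 (n = 4). The properly named genes of at least 1 CPM with the smallest p were higher for Tceal7 (3.73 ± 0.49 SE; edgeR adjusted p = 0.241), the phosphatase activator Ptpa (1.22), Rpl12 (1.48), Rpl13 (1.63) and Ramp1 (1.85), and lower for Mier3 (-2.27), Igfn1, a sarcomere protein (-5.26), Enox2 (-1.39), the lysophospholipase Pnpla7 (-2.28) and Wdr47 (-0.98). None of them passed in edgeR, 744 genes had an unadjusted p under 0.05 (676.8 expected by chance), DESeq2 called 55, limma-voom 0, and a fit of only TZG and NC 2. Col1a1 stood at 2.0, Il1b at 0.86, Ccl2 at -0.38, Ptgs2 at -0.35, Myh7 at 9.06, Myh4 at 0.29, Fbxo32 at -1.28, Trim63 at 0.061, Myog at -0.94 and Ppargc1a at 0.47, none past the threshold.

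Without MPS 14 in the shared fit, 11 genes changed between TZG and NC (edgeR), 9 up and 2 down. Tceal7, a transcription elongation factor-like gene of chromosome X (106774980 to 106777072), rose by 3.74 ± 0.44 (SE; edgeR adjusted p = 0.0203), to 49.1 ± 34.9 normalised CPM (SD, n = 3) from 3.67 ± 1.22 (n = 4). Actn2, the alpha-actinin that crosslinks actin at the Z-disc, rose by 2.37 ± 0.31 to 602 ± 184 normalised CPM (SD, n = 3; edgeR adjusted p = 0.0203) from 116 ± 41.3 (n = 4). Mier3 (ENSRNOG00000013121, chromosome 2, 43266739 to 43294889) fell by 2.26 ± 0.26 (SE; edgeR adjusted p = 0.0134), to 3.44 ± 0.901 normalised CPM (SD, n = 3) from 16.4 ± 2.38 (n = 4), and Morc3, a chromatin ATPase, fell by 1.12. Tceal5 rose by 4.71, Rpl13 by 1.64 and the mitochondrial ribosome gene Mrpl14 by 1.51. So did the ubiquinone synthesis gene Coq7 by 1.5, the RNA-binding protein gene Pcbp4 by 1.27 and Ptpa by 1.23, with edgeR adjusted p between 0.0203 and 0.0416. The ninth gene that rose carries only a locus name. Col1a1 (2.02), Il1b (0.86), Ccl2 (-0.37), Ptgs2 (-0.34), Myh7 (9.06), Myh4 (0.30), Fbxo32 (-1.28), Trim63 (0.068), Myog (-0.93) and Ppargc1a (0.48) did not pass.

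Oxidative phosphorylation rose with 48 of 49 higher (median 0.75; camera adjusted p = 3.72e-23), and ribosomal protein genes rose with 84 of 89 higher (0.52; 1.73e-18), both at an adjusted p = 0.596 with an estimated correlation. In the former, Cox5b stood at 1.3 and Cyc1, cytochrome c1, at 1.15 (edgeR adjusted p = 0.0626 for both). Fast fibre genes rose (median 0.72; camera adjusted p = 3.7e-06), as did glycolysis (0.42; 0.000586), the citric acid cycle (0.41; 2.62e-06), calcium handling (0.45; 0.00303) and denervation genes (0.62; 0.0301), each at an adjusted p = 0.596 with an estimated correlation. Slow fibre (4.87; camera adjusted p = 0.00526) and adipocyte genes (1.72; 0.0196) rose at an adjusted p = 0.621 with an estimated correlation, the mitochondrial genome (0.42; 0.0273) at 0.687, and erythroid genes (1.46; 0.0129) at 0.596. Single libraries carried these 4: without TZG 27 the median of slow fibre, TZG vs NC, without MPS replicate 14, was 0.60 (camera adjusted p = 0.0787), and without TZG 43 that of adipocyte, TZG vs NC, without MPS replicate 14, was 0.37 (0.051). Without TZG 43, mitochondrial genome, TZG vs NC, without MPS replicate 14, had -0.020 (camera adjusted p = 0.984) and erythroid and blood, TZG vs NC, without MPS replicate 14, had 0.65 (0.0598). The denervation call ended too (0.21; 0.285), and the lists called fell from 18 to 12. The globin gene Hbb stood at 1.47 and Pvalb at 1.60. Scd stood at 8.10, with 301 ± 501 normalised CPM (SD, n = 3) against 1.12 ± 1.13 (n = 4), and Fasn at 3.83, with the highest level of both in TZG 43.

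Interferon response genes fell with 26 of 26 lower (median -0.99, camera adjusted p = 4.5e-07, and adjusted p = 0.596 with an estimated correlation), with the RNA sensor Ifih1 at -1.06 and Ifit2 at -1.20, neither past the threshold. Their list stood at 3.13 mean log2 CPM in NC 5, inside the TZG range of 3.05 to 3.23, and at 3.86, 4.99 and 4.34 in NC 4, 6 and 7. Endothelial (-0.37; camera adjusted p = 0.00594), glucocorticoid (-0.50; 0.0117), macrophage (-0.20; 0.0273), fibroblast (-0.38; 0.0273), antigen presentation (-0.39; 0.0348) and atrophy genes (-0.15; 0.0348) also fell as lists. Their camera adjusted p was 0.625, 0.596, 0.705, 0.596, 0.634 and 0.609 with an estimated correlation, so that none of the 18 lists called passed that way. The endothelial median turned to 0.062 without TZG 43 and the macrophage median to 0.23 without TZG 27. Adjusted over the list alone, 40 oxidative phosphorylation, 39 ribosomal, 8 interferon and 8 fast fibre genes passed, against 0, 1, 0 and 0 over all genes. The count of 11 moved with single libraries: it was 315 without TZG 43, 44 without TZG 27, and 5, 0, 3 and 0 without NC 4, 5, 6 and 7. DESeq2 called 857, limma-voom 10, a fit of only TZG and NC 2, and 2581 had an unadjusted p under 0.05.

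**Figure D4:**
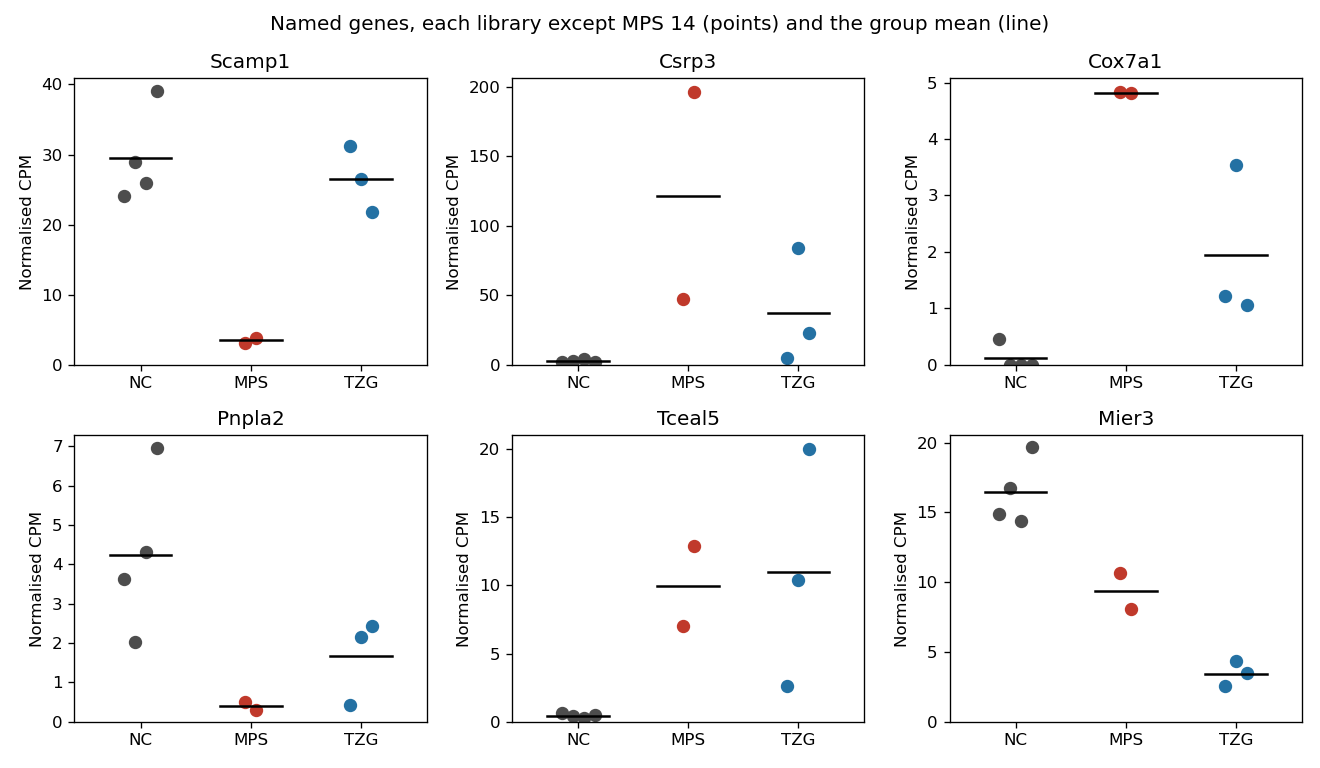
Normalised CPM of Scamp1, Csrp3, Cox7a1, Pnpla2, Tceal5 and Mier3 in each library without MPS 14, with 1 point per library and a line at each group's mean. Scamp1 averages 3.46 in MPS against 29.5 in NC and 26.5 in TZG, and Mier3 averages 3.44 in TZG against 16.4 in NC.

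A last pair of measures asked whether the genes that differ between MPS and NC lie back towards NC in TZG. Without MPS 14, 341 of the 362 genes (94.2%) had the opposite sign in TZG against MPS, but both comparisons use the same MPS libraries, and 20 simulations of a TZG group equal to MPS gave 71.5% to 75.7%. Those simulations called 1238 to 1471 genes, a longer list than the real one. Over their 362 genes of smallest p, a measure added after the data were seen, they gave 69.9% to 77.9%. They took the observed NC and MPS means as the true ones and drew genes independently. They may therefore understate the share for a TZG group equal to MPS, and the gap to 94.2% decides nothing. Scamp1 was the gene that passed in both comparisons, in opposite directions. When genes were chosen on 2 MPS libraries and their direction measured on the one left out, MPS 14 as the one left out gave 12.43% (45 of 362). With its low muscle content, MPS 14 can differ from TZG in a gene whatever the extract does. How many of the genes followed are muscle genes was not counted. The figure is therefore no evidence on the extract. With MPS 14 kept in, leaving out MPS 10 or MPS 11 left 0 genes to follow in edgeR. Without MPS 14, all of the genes chosen with MPS 10 or MPS 11 left out had the opposite sign on that library, 2 of 2 and 7 of 7, which are few. Across genes, the fold changes of MPS against NC and of TZG against MPS correlated at r = -0.70 with all libraries, where simulations with no effect gave -0.55 to -0.51. The simulations gave all groups the same spread per gene, whereas MPS 14 adds spread to the MPS group alone, which both comparisons share. The gap with all libraries is therefore no evidence of a return towards NC. Without MPS 14 these fold changes correlated at -0.56, where simulations gave -0.68 to -0.61. The fold changes of MPS and TZG against NC correlated at 0.66 without MPS 14 (simulated 0.30 to 0.41), and at 0.47 to 0.54 when each was measured against its own pair of NC libraries. The covariance was 0.409 against a simulated mean of 0.0943. With all libraries the agreement was weaker, at 0.470 (simulated 0.399 to 0.452), and at 0.243 to 0.378 with separate NC pairs. All 9 genes that rose in TZG, among them Tceal5, Tceal7, Actn2 and Rpl13, were among the 307 that rose in MPS. Both lists use the same 4 NC libraries and 1 fit, so some overlap is expected without a shared effect, and how much was not simulated. Morc3 was among the genes that fell in both.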

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

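The tests of the 3 patterns weighed here were chosen after the values were seen. The comparisons of single NC libraries were set in advance.

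Lymphoid genes stood high and muscle genes low in MPS 14. Of 15 lymph node markers, 13 stood there at least 10 times above the highest of the other 9 libraries, against 3 of 10 thymus and 1 of 9 bone marrow markers, so RNA of a lymph node is a candidate explanation. Entry of lymphocytes throughout the MPS group is argued against, since the lymphocyte list stood at -0.71 log2 CPM in MPS 10 and -0.98 in MPS 11, below the NC range of -0.27 to 0.33. A swap with another sample of the series stays open. The other 9 libraries correlated with each other at 0.886 or more, but they would do so whichever label MPS 14 carried. The highest correlation of TZG 27 was 0.9666, the same as that of MPS 11. Within its own group TZG 27 reached 0.9462 with TZG 26 and 0.8993 with TZG 43. A wrong label from outside the series, and lymphoid tissue formed inside this 1 muscle, which still gave 5.53% of the usual Acta1 level, stay open and untested.

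Genes of oxidative phosphorylation and of the cytosolic ribosome were higher than NC in both MPS and TZG without MPS 14. Gene length as the whole cause is argued against for oxidative phosphorylation, whose medians of 0.75 lay at percentile 100 among 10000 random lists of matched length in both comparisons. With the length trend removed they were 0.49 (SD over members 0.62) and 0.47 (SD 0.42), and camera still called the list (adjusted p = 5.4e-10 and 3.45e-13). The random lists drew genes independently, whereas members of a real list can move together, so such percentiles overstate how far a list stands out. Camera was run here at its preset correlation. With an estimated correlation, before the length correction, its adjusted p was 0.393 and 0.596, so a chance difference between the groups stays open. For ribosomal proteins the 2 comparisons part. The median lay at percentile 96.65 in MPS against NC, within the central 95%, and at 99.42 in TZG against NC, above it. With the trend removed it shrank from 0.43 to 0.13 (SD 0.62) and from 0.52 to 0.20 (SD 0.42), and camera still called the list (adjusted p = 0.0158 and 7.1e-06). Since lists of matched length alone reached the median seen in MPS against NC, gene length stays open for this list. Slow fibre content as the cause is argued against for TZG against NC only. With the slow fibre level as a covariate, the medians there were 0.87 for oxidative phosphorylation (SD 0.55, from 0.73) and 0.72 for ribosomal proteins (SD 0.50, from 0.50). In MPS against NC that covariate nearly separates the groups and leaves 0 single genes, so slow fibre content stays open there. A difference in how the NC muscle pieces were taken or stored, and an effect of the pain model that the extract leaves in place, may both remain and were not tested.

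Slow fibre genes stood high in MPS 10, MPS 11 and TZG 27. Their list ranged over 5.73 log2 units within the TZG group alone, against 5.80 between MPS and NC without MPS 14, which is consistent with pieces of muscle that hold uneven shares of slow fibres. A fibre type difference of the MPS group that the treatment reverses would need low TZG libraries: 1 of 3, TZG 27, lay at or above the lowest MPS library in slow minus fast level (-5.00, against -6.30 in MPS 10), so with 3 libraries the 2 explanations cannot be told apart. The Schwann cell list also stood high in MPS 10 and MPS 11 (4.26 and 3.61 log2 CPM, NC 0.95 to 3.07), but so it did in TZG 43 (3.70), and how the pieces were cut was not in the labels.

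Single NC libraries stood far from the other 3 in 7 of 98 values tested. Chance alone gives about 1 in 20 for values chosen without regard to NC. Many of these genes were named for their difference from NC, so that rate is no reference here. The figure closing each bracket is the gap to the nearest library divided by the range of the 4, and lies above Dixon's critical value at 5%. NC 5 had the lowest total count, 12616160 against 13426347 to 13581646 (0.839). NC 5 also stood apart for Ptgs2 (2.99 normalised CPM against 0.613 to 0.844; 0.903), for the cytochrome P450 gene Cyp4f18 (8.32 against 2.76 to 2.95; 0.965) and for Enox2 (17.6 against 12.1 to 12.7; 0.892). NC 7 stood apart for Myh7 (2.85 against 0.141 to 0.323; 0.933), in the direction of the MPS libraries, and for Ramp1 (5.71 against 8.56 to 9.08; 0.846). NC 4 stood apart for Morc3 (47.3 against 54.5 to 55.9; 0.834).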

How the results depend on the processing

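The slow fibre covariate, the length correction and every alternative to the fits without MPS 14 were chosen after the data were seen. So was leaving out MPS 14 for TZG against NC, for the share of opposite direction and for the correlation of fold changes. The others were planned. Where no cause is given, the cause was not tested. No paired analysis was possible because no title number occurs in more than 1 group. Where leaving out a library left 1 MPS library, that library was assumed to vary like the other groups. The FPKM scaling and pseudocount alternatives, written down in case there were no counts, were not run.

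With all libraries, the counts of 0 genes became 205 (MPS against NC), 3 (TZG against MPS) and 55 (TZG against NC) with DESeq2, and 1453, 700 and 744 with an unadjusted p (676.8 expected by chance in each). They stayed at 0 with RLE factors, no filter, the stricter filter, limma-voom, and a minimum fold change. A fit of only the 2 groups called 0, 0 and 2. Leaving out 1 library gave 0 to 362 genes for MPS against NC, 0 to 1 for TZG against MPS and 0 to 11 for TZG against NC, each time with the highest count without MPS 14. The 13, 20 and 10 lists became 0, 0 and 0 with an estimated correlation and 2, 0 and 0 with fry. Leaving out 1 library gave 10 to 20 lists (20 without MPS 10 or MPS 11), 15 to 22, and 8 to 18 (18 without MPS 14).

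Without MPS 14, the 362 genes of MPS against NC became 1100 with DESeq2 (361 of the 362 among them), 1277 in a fit of the 2 groups (362), 2826 with an unadjusted p (686 expected by chance in each of the 3 comparisons), 225 with the length trend removed (191) and 0 with the slow fibre covariate, which nearly separates the groups (all 362 kept their direction). Leaving out 1 library gave 2 to 104, the highest without NC 4. The 1 gene of TZG against MPS became 14 with DESeq2, 2 with no filter, 575 with an unadjusted p, and 0 with limma-voom, in a fit of the 2 groups, with the length trend removed and with the slow fibre covariate; leaving out 1 library gave 0 to 2. The 11 genes of TZG against NC became 857 with DESeq2 (11 of the 11 among them), 65 with no filter (11), 97 with the stricter filter (11), 2581 with an unadjusted p, 2 in a fit of the 2 groups (2), 3 with the length trend removed (3) and 13 with the slow fibre covariate (4, so that the other 7 calls were lost); leaving out 1 library gave 0 (NC 5 or NC 7) to 315 (TZG 43). The 15, 15 and 18 lists became 1, 0 and 0 with an estimated correlation and 8, 0 and 0 with fry, and leaving out 1 library gave 14 to 17, 10 to 22 and 12 to 20.

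The share of genes with opposite direction, 12.43%, ranged from 6.12% without NC 6 to 100% without MPS 14 (9 of 9 genes), with 42.9% without MPS 11, 29.8% without MPS 10, 7.69% without NC 4 and 7.14% without NC 5. These are shares of unlike gene sets: 6365 genes without MPS 11 and 6360 without MPS 10, chosen on 1 MPS library at a time, and 49, 104 and 42 without NC 6, NC 4 and NC 5, against 362. The correlation of -0.70 ranged from -0.78 without MPS 11 to -0.56 without MPS 14, with -0.59 without TZG 26 and -0.63 without TZG 27.

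Some called lists turned direction when 1 library was left out; their medians are given as ranges over the left-out libraries. In each of the next 2 sentences the value of the other sign is the one without MPS 14. For MPS against NC it was glycolysis and glycogen (-0.64 to 0.27) and fatty acid oxidation (-0.40 to 0.13); there the medians of muscle regeneration (0.033) and cell proliferation (-0.066) changed sign too, while the test kept its direction and no longer passed. For TZG against MPS it was NF-kB (-1.05 to 0.23), antigen presentation (-1.87 to 0.33), cell proliferation (-1.97 to 0.55), interferon response (-1.19 to 0.074), calcium handling (-0.063 to 0.82), circadian clock (-0.017 to 0.39), fatty acid oxidation (-0.0068 to 0.65), muscle regeneration (-0.039 to 0.91), oxidative phosphorylation (-0.0094 to 0.87) and denervation (0.088 to 0.89, where the median kept its sign and the test turned). Of these, 3 passed camera in the new direction without MPS 14. They were glycolysis and glycogen, MPS vs NC (adjusted p = 0.0317, range over its alternatives 4.88e-06 to 0.713), antigen presentation, TZG vs MPS (0.0174, range 1.44e-05 to 0.712), and NF-kB and Toll-like receptor signalling, TZG vs MPS (0.00995, range 0.000159 to 0.712). With all libraries, the lists that turned without TZG 43 were adipocyte, TZG vs MPS (-0.098 to 1.77) and endothelial, TZG vs NC (-0.72 to 0.068). In the fits without MPS 14, endothelial turned without TZG 43 in TZG against MPS (-0.73 to 0.062) and in TZG against NC (-0.71 to 0.062). So did mitochondrial genome, TZG vs MPS, without MPS replicate 14 (-0.049 to 0.67). Macrophage in TZG against NC turned without TZG 27 (-1.04 to 0.23).

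Over all named genes and called lists, no gene that had passed changed direction. Without MPS 14, named genes kept their side of the threshold in 661 gene and setting pairs, lost it in 207 and gained it in 2, and lists kept it in 346 and lost it in 133. With all libraries the named genes, none of which had passed, gained it in 40 pairs and stayed in 758, and lists kept it in 307 and lost it in 142. At these depths and group sizes, simulated 4-fold changes were found in 16.9% to 68.8% of genes over the 6 comparisons and 8-fold changes in 53.2% to 88.1%.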

Other observations

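The test over other splits of the samples was set in advance, although the fit without MPS 14, to which it was also applied, was not. The genes and libraries described next were chosen after their values were seen. TZG 43 held more of some genes of skin and fat than the other libraries did. The keratins of the basal layer of skin, Krt5 and Krt14, stood at 34.9 and 22.1 CPM there and at no more than 0.788 CPM elsewhere. The fat synthesis enzymes Scd and Fasn stood at 644.6 and 280.3 CPM, against at most 84.3 and 107 in MPS 14 and at most 14.5 and 19.3 in the other 8 libraries. The fat droplet coat gene Plin1 stood at 33.5 CPM, the fat cell hormone gene Adipoq at 73.9 (45.73 in NC 5 and 27.84 in TZG 27) and Col1a1, the main fibrillar collagen, at 1899 CPM, each the highest of all 10 libraries. TZG 43 also had the largest mitochondrial share of counts (38.1%).

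Some genes varied widely between libraries of 1 group. The tight junction gene Cldn5 was listed at 0 in 6 libraries and stood at 63.0, 76.96 and 32.6 CPM in NC 4, NC 5 and TZG 27. The slow light chain gene Myl3 stood at 26.4 CPM in NC 4 and 27.9 in TZG 26, and at no more than 0.372 in the other NC libraries. Lyz2 stood at 5323 CPM in MPS 14, against 30.8 to 199.9 in the others, and Hbb at 61.7 CPM, against 187.5 to 960.8.

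The authors' deposited table calls 1348 genes between MPS and NC, 1167 up and 181 down. Of those up, 1042 (89.3%) had their highest value in MPS 14, and for 753 the mean of MPS 10 and MPS 11 was not above that of NC. The table calls 736 genes between TZG and MPS, 80 up and 656 down, of which 646 (98.5%) of those down were highest in MPS 14 and 422 had a mean of MPS 10 and MPS 11 not above that of TZG. Its smallest q there is 0.17, so none of the 736 has a q under 0.05, while 290 genes do in MPS against NC and 368 in TZG against NC, where 706 are called (511 up, 195 down). An unadjusted p under 0.05 with a 2-fold change holds for 1725, 864 and 1133 genes of the table, more than are called, so a further filter that the headers do not state was used.

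Genes whose groups did not overlap in any library made up 11% of those tested in MPS against NC with all libraries (5.71% by chance), 5.3% in TZG against MPS (10% by chance) and 17.4% in TZG against NC (5.71% by chance). Without MPS 14 the shares were 38.6% (13.3% by chance), 15.7% (20% by chance) and 17.3% (5.71% by chance).

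Other splits of the compared libraries into groups of the same sizes were fitted in the same way. Without MPS 14, the 11 genes of TZG against NC were reached by 1 of 35 splits, the real one, the highest other giving 1 gene. That is the smallest share 35 splits can give, in a fit chosen after the data were seen and as 1 of several counts tested, and the 11 genes became 0 without NC 5 or NC 7. Taken alone, with no adjustment for the other counts, that share lies under 0.05, but chance is not excluded for it. Chance is not excluded either for the 18 lists of the same comparison (4 of 35 splits gave as many, highest other 20), nor with all libraries for the 10 lists of TZG against NC (23 of 35, highest other 15) and the 13 lists of MPS against NC (34 of 35, highest other 23). With all libraries, edgeR called 0 genes in each comparison, a count that every split reaches, so the splits decide nothing there (highest other 0 for MPS against NC, 0 for TZG against MPS and 1 for TZG against NC). An unadjusted p under 0.05 held for 1453, 700 and 744 genes (676.8 expected by chance in each), and DESeq2 called 205, 3 and 55. The remaining comparisons have too few splits for a share under 0.05. With all libraries this was TZG against MPS with 20 lists (4 of 10 splits gave as many, highest other 23). Without MPS 14 they were MPS against NC with 362 genes (1 of 15, highest other 0) and 15 lists (7 of 15, highest other 19), and TZG against MPS with 1 gene (6 of 10, highest other 7) and 15 lists (4 of 10, highest other 17).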
